A study of Mus musculus with 3 samples.

How the data were processed

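PolyA-selected RNA-seq was measured in 3 libraries of activated regulatory T cells from a male mouse of 4 months, of the strain Foxp3CreERT2 x Rosa26YFP. Per the labels, the libraries are technical replicates 1, 2 and 3 of 1 biological replicate, and the RNA was sheared and selected to fragments of 100 to 300 bp. All 3 libraries form 1 group with no control, so levels and the spread between libraries were reported and no contrast between conditions was made. The sort or gate that defined the cells is not given in the sources used here. The replicate numbers were taken from the sample descriptions.

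The main gene and transcript tables, deposited by the authors on gene models of release M21 and mouse genome mm10, hold expected counts and TPM per library. Per the file headers they also hold the percent of each gene's transcripts and other estimates, namely effective lengths and posterior SDs, which were not used. These tables were computed from transcriptome alignments, and the program is not given in the sources used here, although the column names are those that RSEM writes. A second deposited transcript table holds estimated (expected) counts and TPM computed straight from the read files and an index. Its program is likewise not given, and its column names are those that kallisto writes. A deposited gene table on release M4 holds whole-number counts taken from an alignment by a counter that is not given in the sources used here. Each library was deposited on its own, with no scaling between libraries.

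The main table held 81881 entries, of which 55536 were mouse genes of the M21 annotation and 22028 of these protein-coding. The other entries were 26248 short numeric IDs, 96 ERCC spike-in sequences and 1 phiX sequence, and they were left out of all gene-level work. The transcript tables were read for 141862 M21 transcripts in the main and 141864 in the second quantification. M4 genes were matched to M21 by gene ID without version, which matched 22195 of 22457 genes (98.8%). The ratio of M4 count to main fragment count was checked against the coding share of each gene's exons and was higher at higher coding shares, so M4 counts were divided by coding bases before levels were compared. That they count reads over coding sequence is an inference from this ratio.

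The gene-level depth was 10981924, 9700630 and 6667391 expected counts in replicates 1, 2 and 3. A count of 0 allowed up to 3 counts per library, or a CPM (total-scaled count) of 0.273, 0.309 and 0.450. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Folds against a library under 1 count used the floor of 3 counts per library and were given as lower bounds. Folds against 1 to 3 counts were given with an exact 95% binomial interval.

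Levels were the mean and SD of the deposited TPM over the 3 libraries. The labels call the libraries technical replicates, which would limit the SD to library preparation and sequencing. The SD is the spread between these libraries, and the steps it covers are not given in the sources used here. Genes were called detected at a TPM of at least 1 in all 3 libraries. For each gene list, the median of log2(TPM + 1) was taken per library, averaged, and placed as a percentile among 10000 random lists of the same size drawn from protein-coding genes above 0 in any library. Lists covered regulatory T cell (Treg) identity, activated or effector Treg genes, resting or naive T cell genes, the T cell receptor complex, Th1, Th2, Th17 and Tfh genes. They also covered secreted mediators, chemokine receptors and adhesion, checkpoint receptors, cell cycle, glycolysis, fatty acid oxidation, interferon-stimulated, immediate early, housekeeping and sex-check genes. Marker lists covered CD8 T cells, NK or innate lymphoid cells, B cells, plasma cells, myeloid cells, dendritic cells, erythroid cells, immature thymocytes and stromal, endothelial or epithelial cells. These lists, the tests and most alternatives were chosen before the data were examined. Effector Treg genes were set against resting T cell genes by the difference of list medians within each library, with 100000 two-sided permutations of genes between the lists.

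Expected counts were rounded to whole numbers for all count tests. Library pairs were compared by a chi-square test over genes with a summed count of at least 10. Each gene with a mean count of at least 10 was tested over the 3 libraries by a chi-square test with 2 degrees of freedom against TMM effective library sizes. Benjamini-Hochberg adjusted p below 0.05 over all tested genes was the threshold, and each list was also adjusted over the list alone. This model holds sampling noise only. A stricter model, chosen after the data were seen, added the trended negative binomial dispersion of edgeR to the variance. That dispersion was estimated from the same 3 libraries, so the differences under test are part of it. The common dispersion came from edgeR with an intercept-only design. T cell receptor V genes were compared over the libraries by a chi-square test beside 1000 sets of other genes matched on mean count. The log2 deviation of a gene in a library was its log2 TMM-scaled CPM, with a prior of 0.5, minus the mean over the 3 libraries. The median deviation of each list was placed among 10000 random lists matched on mean count.

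On simulated counts with sampling noise only, the pair ratio lay between 1.00 and 1.01. The per-gene test recovered 73.3% of genes simulated at 1.5-fold, 86.5% at 2-fold and 100% at 4-fold, with 3.85% false among its calls. Under the trended dispersion it recovered 0% at 1.5-fold, 5.77% at 2-fold and 48.1% at 4-fold. Simulated dispersions of 0.01, 0.04 and 0.10 were estimated at 0.0101, 0.0402 and 0.0983. Of random gene lists, 6.33% lay outside the central 95% of matched lists.

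The named-gene rule, written in advance, took the 4 highest and 2 lowest members of each list by mean TPM and any member singled out as a marker. It also took the 10 genes with the highest TPM, and the 10 genes with the largest range between libraries among varying genes with a mean count of at least 100. The 5 V genes with the largest range and a fixed set from Foxp3 to Ccr7 completed it. Genes named outside the rule are said to be so, and the values of a few genes under it are not reported here.

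The alternatives chosen then were M4 counts per coding base, TMM-scaled CPM, TPM without mitochondrial genes, and leaving out each library in turn. Others were a pseudocount of 0.1, list members below TPM 1 left out, the mean in place of the median, and detection at TPM 0.5 or 5. For the count tests they were DESeq2 size factors, raw totals, count minimums of 1 and 50, only genes with whole-number expected counts, and the DESeq2 gene-wise dispersions. Gene sums of the second transcript quantification for levels, M4 counts for V genes, levels after the median shift of all genes was removed, and the trended dispersion were added after the data were seen. So were 4 gene lists: glucocorticoid or stress genes seen in the data, held-out glucocorticoid-responsive genes, held-out interferon-stimulated genes and other red cell genes. A test for a single library far from the others was not applied, since a group of 3 is too small for it, and no other splits of the samples exist with 1 group. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.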

Results

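PolyA-selected RNA was sequenced from activated regulatory T cells, a subset of CD4 T cells that restrains immune responses and depends on the transcription factor Foxp3. The cells came from a male mouse of 4 months carrying Foxp3CreERT2, an inducible recombinase allele at Foxp3, and Rosa26YFP, a fluorescent reporter. The 3 libraries form 1 group, with 10981924, 9700630 and 6667391 fragments assigned to genes in replicates 1, 2 and 3. Protein-coding genes took 91.5%, 92.2% and 89.7% of fragments, rRNA took 2.23%, 2.05% and 3.10%, and mitochondrial genes took 2.87%, 2.21% and 2.67%. The 10 most abundant genes of each library took 9.41%, 8.79% and 9.97% of its fragments.

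The first question was which genes this population expressed and at what level. Actb, which encodes beta-actin and lies on mm10 chromosome 5 from 142903115 to 142906754, had the highest level, at 19140 ± 3384 TPM (SD, n = 3). Also among the 10 highest by mean TPM were Tmsb4x, Eef1a1, the ribosomal protein gene Rps19, and B2m, which encodes the constant chain of MHC class I and stood at 6456 ± 1149 TPM. The 10 also held the rRNA genes CT010467.1 and mt-Rnr2, the locus AY036118, and mt-Co3 of the respiratory chain. A TPM of at least 1 in all 3 libraries was reached by 11943 genes, of which 9988 were protein-coding. A mean TPM of at least 1 was reached by 13686 genes. The 9 housekeeping genes had a median log2(TPM + 1) of 9.41 ± 0.07 (SD, n = 3), at percentile 100 of random lists. They ran from Actb, B2m, Rplp0 and Ppia to Gusb and to Tbp, at 37.6 ± 3.42 TPM.

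Foxp3, the lineage factor of regulatory T cells, lies on mm10 chromosome X from 7573644 to 7595245 and was at 36.0 ± 11.9 TPM (SD, n = 3). In the main quantification this was the lowest mean in the 15-gene Treg identity list, at rank 3753 among all genes. In M4 counts per coding base it was not the lowest, with Foxp3 at 74.8 ± 27.9 TPM and Socs2 at 42.4 ± 5.78 TPM. Il2ra, the high-affinity IL-2 receptor chain by which regulatory T cells are usually recognised, lies on chromosome 2 from 11642807 to 11693193 and was at 249 ± 19.9 TPM. Ikzf2, which encodes Helios, on chromosome 1 from 69531214 to 69687245, was at 356 ± 86.5 TPM, and Ikzf4, which encodes Eos, was at 87.9 ± 11.7 TPM. Tnfrsf18, which encodes the receptor GITR, on chromosome 4 from 156026164 to 156028895, was at 539 ± 154 TPM. Ctla4, the inhibitory receptor that competes with CD28, on chromosome 1 from 60887000 to 60915832, was at 351 ± 228 TPM. Replicate 3 carried much of the Ctla4 level, at 612 TPM against 190 and 250 in replicates 1 and 2, and the mean without replicate 3 was 220 TPM. The highest members of the list were the folate receptor gene Izumo1r, at 764 ± 283 TPM, Capg, at 559 ± 185 TPM, Tnfrsf18, and Il2rb, at 513 ± 60.5 TPM.

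All 15 Treg identity genes were detected in all 3 libraries, and their median log2(TPM + 1) was 7.33 ± 0.52 (SD, n = 3), at percentile 100 of random lists. Between libraries, 14 of the 15 varied beyond sampling noise over all genes tested, Socs2 being the exception, and 15 did when adjusted over the list alone. Only Ctla4 of this list varied under the trended dispersion of edgeR, with an adjusted p of 0.00152. The absolute levels depended on the quantification: Ikzf2 was at 161 ± 19.1 TPM from M4 counts per coding base.

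A second question was whether genes of activated, effector regulatory T cells stood above those of resting T cells in a population labelled as activated. Tnfrsf4, which encodes OX40, was at 658 ± 143 TPM (SD, n = 3), Icos at 450 ± 82.1 TPM and the inhibitory receptor gene Tigit at 462 ± 89.3 TPM. Lgals1 and S100a6, both raised in memory-like T cells, were at 658 ± 73.2 and 496 ± 87.5 TPM. The cytotoxic granule gene Gzmb was at 173 ± 53.4 TPM, the terminal effector marker Klrg1 at 21.4 ± 3.47 TPM and the suppressive cytokine gene Il10 at 15.5 ± 6.97 TPM. The tissue repair genes Il1rl1, which encodes the IL-33 receptor, and Areg were the lowest of the effector list, at 6.54 ± 0.814 and 1.72 ± 0.441 TPM. Among the resting genes, the lymph node homing gene Ccr7 was at 253 ± 72.6 TPM, and Tcf7 was at 211 ± 40.8 TPM. Il7r, the IL-7 receptor gene, was at 192 ± 128 TPM, and at 120.2 TPM without replicate 3, while Foxo1 and Bach2 were lowest, at 21.8 ± 4.96 and 10.3 ± 1.10 TPM.

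The 25 effector genes were all detected, with a median log2(TPM + 1) of 5.99 ± 0.40 (SD, n = 3) at percentile 100, and the 14 resting genes were all detected at 7.14 ± 0.25, also at percentile 100. Between libraries, 21 effector genes varied over all genes and 21 adjusted over the list alone. For the resting genes these counts were 13 and 14, and Il7r and Id3 also varied under the trended dispersion of edgeR. There 0 effector genes varied, with 2 at an unadjusted p under 0.05. Effector minus resting was -1.16 ± 0.56 (SD, n = 3), with -0.62, -1.11 and -1.74 in replicates 1, 2 and 3. Permuting genes between the lists gave a two-sided p of 0.283, so the lists were not shown to differ. The permutation was across genes, which are not independent replicates. The lists hold different genes with levels of their own. Without a control, the sign of the difference does not show whether the cells were activated.

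**Figure D1:**
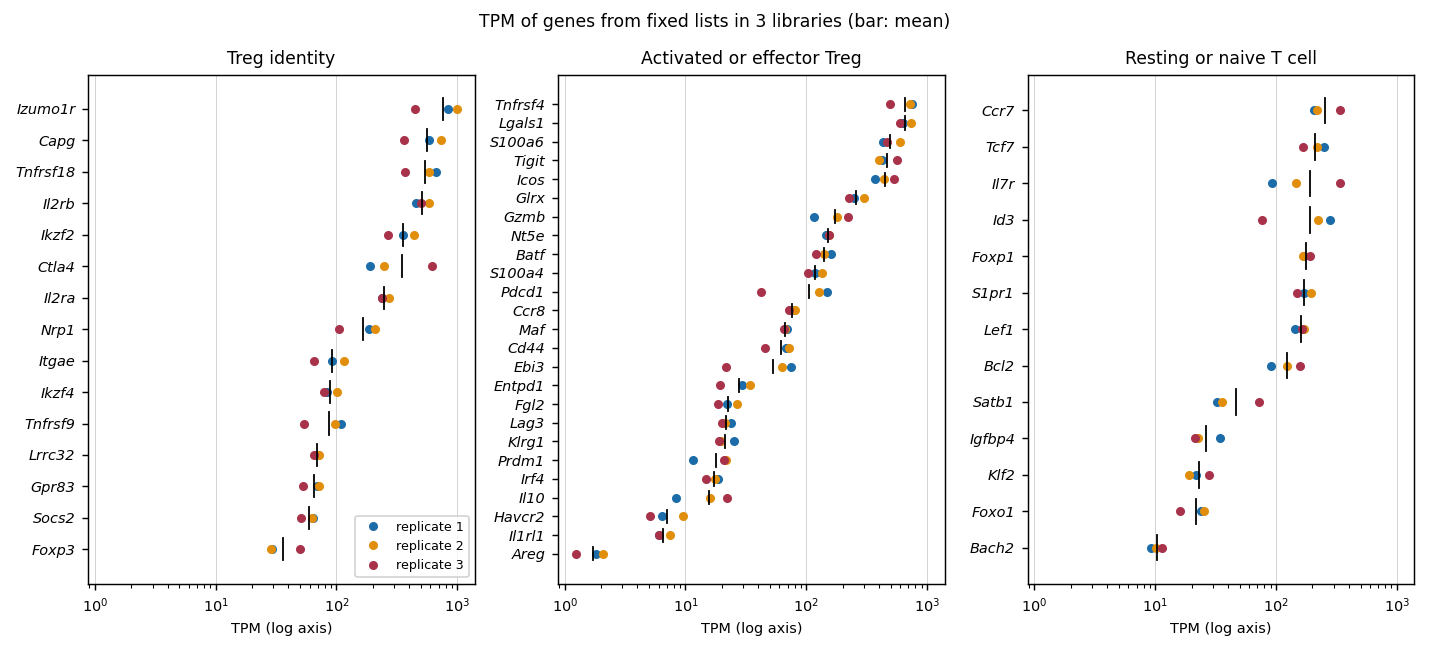
TPM of genes on a log horizontal axis from the Treg identity, activated or effector Treg, and resting or naive T cell lists, with a point per library and a bar at the mean of the 3. Foxp3 was at a mean of 36.0 TPM, and the Ctla4 point of replicate 3 stood at 612 TPM.

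Genes of the T cell receptor complex marked the population as T cells. The constant-region genes Trbc2, Trac and Trbc1 were at 3440 ± 602, 2698 ± 562 and 1873 ± 338 TPM (SD, n = 3), and the kinase gene Lck was at 1215 ± 275 TPM. Cd4 was at 327 ± 89.2 TPM, and Thy1 was at 131 ± 54.2 TPM. All 17 genes were detected, with a median log2(TPM + 1) of 8.86 ± 0.32 at percentile 100, and 16 varied between libraries over all genes and 16 adjusted over the list alone. The checkpoint receptor list was likewise detected in full, at 6.71 ± 0.50 and percentile 100, with all 14 genes varying over all genes and 14 adjusted over the list alone. Its members ran from Tnfrsf4 down to Lag3, at 21.8 ± 1.80 TPM, and Havcr2, which encodes TIM-3, at 6.97 ± 2.29 TPM. Among chemokine receptor and adhesion genes, Selplg, the ligand for selectins, was highest at 556 ± 136 TPM, followed by Itgb7 at 375 ± 63.7 TPM. Ccr10 and Ccr3 were lowest, at 1.61 ± 1.54 and 1.26 ± 0.594 TPM, and without replicate 2 Ccr10 was at 0.755 TPM. Of these 22 genes 20 were detected, at a median of 6.42 ± 0.30 and percentile 100, and 21 varied over all genes and 21 adjusted over the list alone.

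Helper T cell programmes were seen mainly as receptors and regulators and less as cytokines. Of the Th1 genes, Cxcr3 was at 221 ± 66.9 TPM (SD, n = 3) and Stat4 at 113.5 ± 11.1 TPM, while the Th1 factor gene Tbx21 was at 4.38 ± 1.27 TPM. Il12rb2 was lowest at 2.67 ± 2.64 TPM, and at 1.15 TPM without replicate 3. Of the Th2 genes, Gata3 was at 94.3 ± 20.3 TPM and Ccr4 at 23.5 ± 7.08 TPM, Il4 was at 4.03 ± 3.68 TPM and at 1.95 TPM without replicate 1, and Il5 and Il13 had 0 counts in all 3 libraries in the main quantification. Il5 had 0, 3 and 1 counts in the M4 table, at the floor, so Il5 was not detectable above it. Of the Th17 genes, Ccr6 and Rora were at 66.0 ± 19.4 and 51.6 ± 4.99 TPM, and Il17a and Il22 were at 0 in the main quantification. Of the Tfh genes, Sh2d1a and Cxcr5 were at 261 ± 56.3 and 53.3 ± 17.9 TPM, Bcl6 was at 8.30 ± 3.44 TPM, and Ascl2 was lowest at 0.140 ± 0.123 TPM. The secreted mediators Ccl5, Ltb, Penk and Ebi3 led their list at 436 ± 210, 235 ± 63.0, 67.0 ± 29.7 and 53.2 ± 27.9 TPM.

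The list medians of log2(TPM + 1) were 3.92 ± 0.31 (SD, n = 3) for Th1 at percentile 82.9, 1.07 ± 0.49 for Th2 at percentile 20.4 and 0.50 ± 0.44 for Th17 at percentile 14.6. Without replicate 3 the Th17 median was 0.25. The Tfh median was 2.97 ± 0.15 at percentile 59.5, and the secreted mediators were at 2.85 ± 0.25 and percentile 59.1. Detected genes numbered 8 of 8 for Th1, 3 of 6 for Th2, 2 of 7 for Th17, 4 of 6 for Tfh and 15 of 21 for secreted mediators. Counts of varying genes over all genes were 8 of 8 tested, 3 of 3, 2 of 3, 4 of 4 and 11 of 14 in that order, and adjusted over the list alone they were the same, at 8, 3, 2, 4 and 11.

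Proliferation and metabolic genes were expressed in all 3 libraries. The replication clamp gene Pcna was at 154 ± 5.27 TPM (SD, n = 3), Rrm2 at 152 ± 38.9 TPM, Mcm6 at 134 ± 18.4 TPM and Tyms at 129 ± 11.3 TPM, while Bub1 and E2f1 were lowest at 5.67 ± 0.684 and 1.84 ± 0.159 TPM. The glycolytic genes Ldha, Pkm, Aldoa and Eno1 were at 991 ± 84.0, 858 ± 191, 702 ± 150 and 580.1 ± 104 TPM, and Hk2 and the lactate exporter gene Slc16a3 were at 4.83 ± 1.96 and 3.27 ± 1.59 TPM. Of the fatty acid oxidation genes, the electron transfer genes Etfb and Etfa were highest at 179.8 ± 32.0 and 117 ± 21.1 TPM, and the carnitine transfer genes Cpt1a and Cpt2 were lowest at 15.1 ± 2.49 and 14.0 ± 4.26 TPM. All members of the 3 lists were detected. Their medians were 5.94 ± 0.33 for cell cycle at percentile 100, 6.50 ± 0.21 for glycolysis at percentile 100 and 5.61 ± 0.22 for fatty acid oxidation at percentile 99.9. Varying genes numbered 18 of 20, 15 of 16 and 15 of 15 over all genes, and 18, 15 and 15 adjusted over the list alone.

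Interferon-stimulated genes, which respond to type I or type II interferon, were present at widely different levels. Ifi27l2a was at 1083 ± 501 TPM (SD, n = 3), Irf7 at 75.9 ± 26.7 TPM and Bst2 at 69.1 ± 26.4 TPM. Rsad2 and Ifi44 were lowest, at 3.26 ± 2.09 and 3.15 ± 2.08 TPM, and Rsad2 was at 2.12 TPM without replicate 2. The list median was 5.20 ± 0.95 at percentile 99.2, and 12 of 12 genes varied over all genes and 12 adjusted over the list alone. Under the trended dispersion 2 genes varied, Ifit1 and Oas1a, and 6 did when adjusted over the list alone. Immediate early genes, which respond within minutes to stimulation, were led by Btg2, Zfp36 and Nr4a1 at 140.4 ± 22.9, 117 ± 33.0 and 59.3 ± 17.8 TPM. Dusp1 was at 55.1 ± 44.0 TPM, and at 30.1 TPM without replicate 3, while Fosb and Atf3 were lowest, Atf3 at 0.193 ± 0.104 TPM. Of this list 12 of 14 were detected, at a median of 4.52 ± 0.11 and percentile 96.4, with 11 of 13 tested varying over all genes and 11 adjusted over the list alone. Of the 9 housekeeping genes 8 varied, Tbp being the exception, and 8 varied adjusted over the list alone.

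A further question was whether the libraries held RNA of other cells. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 138 ± 27.1, 93.8 ± 12.1, 48.7 ± 5.84 and 21.9 ± 5.93 TPM (SD, n = 3), and the label gives the sex as male. Xist, which silences an X chromosome in females, was at 0.467 ± 0.393 TPM, and at 0.240 TPM without replicate 3. The sex-check list had 4 of 5 genes detected at a median of 5.63 ± 0.16 and percentile 96.8, and of 4 tested 3 varied over all genes and 4 adjusted over the list alone. The B cell genes Igkc and Ighm were at 1081 ± 1009 and 961 ± 159 TPM. Cd79b was at 55.7 ± 4.97 TPM, Cd79a at 13.8 ± 5.04 TPM and the B cell factor gene Pax5 at 1.41 ± 0.566 TPM. Without replicate 3 the Igkc mean was 514 TPM. Among plasma cell genes, Jchain, which joins secreted antibodies, was at 39.2 ± 32.7 TPM, or 24.1 TPM without replicate 3, and Mzb1 was at 14.7 ± 13.5 TPM, or 7.03 TPM without it. The haemoglobin genes Hbb-bs, Hba-a2, Hba-a1 and Hbb-bt were at 100.3 ± 163, 90.5 ± 152, 52.8 ± 87.5 and 27.6 ± 46.3 TPM. Without replicate 1 they were at 6.28, 2.53, 2.28 and 0.920 TPM. These genes include near-identical copies, so their separate levels are uncertain, and in M4 counts per coding base they were at 49.9, 3.49, 18.9 and 12.6 TPM.

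Among markers of other lineages, Cd8b1 was at 13.4 ± 0.941 TPM (SD, n = 3), but its partner Cd8a, needed for the CD8 receptor, was at 1.32 ± 0.746 TPM. The adaptor gene Tyrobp of NK and myeloid cells was at 5.18 ± 2.56 TPM, Lyz2 of myeloid cells at 11.9 ± 8.32 TPM and Zbtb46 of dendritic cells at 2.15 ± 0.286 TPM. Rag1 and Rag2 of immature thymocytes had 0 counts in all libraries in the main quantification, though the second gave Rag2 0.0427, 0.147 and 0.213 TPM, while Cd1d1 was at 85.5 ± 11.2 TPM. Pecam1, an endothelial marker that leukocytes also express, was at 88.2 ± 19.9 TPM, and Epcam of epithelium was at 1.70 ± 0.473 TPM.

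Against 8.86 for the T cell receptor list, the median log2(TPM + 1) was 3.30 ± 0.46 (SD, n = 3) for B cell markers at percentile 67.0, 2.21 ± 0.57 for plasma cell markers at percentile 43.5 and 3.04 ± 3.38 for erythroid markers at percentile 61.0. Without replicate 1 the erythroid median was 1.16. CD8 T cell markers were at 1.45 ± 0.29 and percentile 32.5, NK or innate lymphoid markers at 0.30 ± 0.13 and percentile 8.43, and myeloid markers at 0.61 ± 0.27 and percentile 9.53. Dendritic cell markers were at 0.20 ± 0.14 and percentile 4.48, or at 0.12 without replicate 3. Immature thymocyte markers were at 0.33 ± 0.03 and percentile 6.97, and stromal, endothelial or epithelial markers at 0.11 ± 0.07 and percentile 0.77. Varying genes over all genes numbered 9 of 9 tested for B cell, 3 of 3 for plasma cell, 6 of 6 for erythroid and 1 of 3 for CD8 T cell markers, and adjusted over the list alone 9, 3, 6 and 0. NK or innate lymphoid markers had 2 of 2 tested, myeloid 1 of 3, dendritic cell 1 of 2, immature thymocyte 2 of 2 and stromal, endothelial or epithelial markers 2 of 3, with 2, 1, 1, 2 and 2 adjusted over the list alone.

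**Figure D2:**
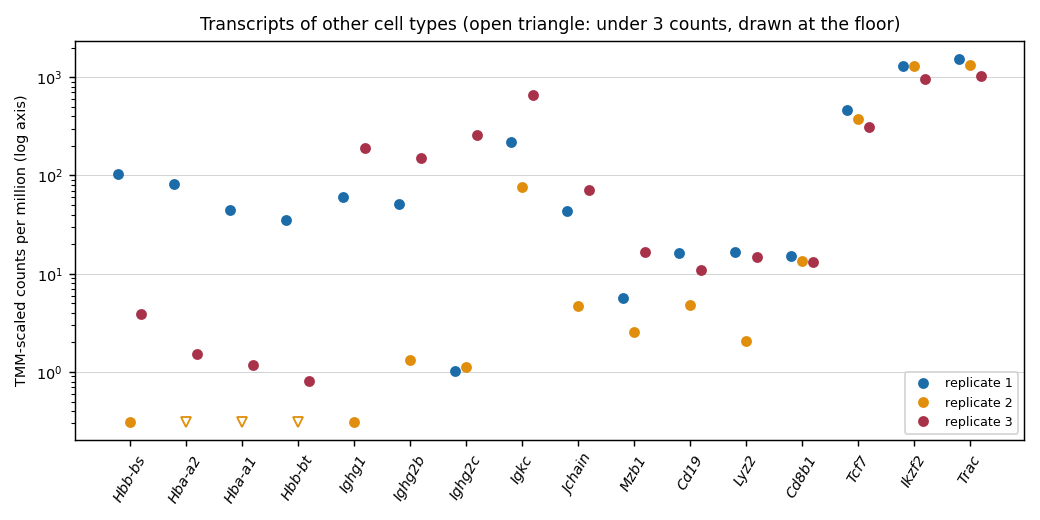
TMM-scaled CPM on a log vertical axis for genes of other cell types beside T cell genes, with a point per library and an open triangle at the floor of 3 counts for values under it. Hbb-bs was at 104 CPM in replicate 1 and at 0.307 and 3.85 in replicates 2 and 3, while Igkc was at 218, 76.6 and 663.

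The next question was whether technical replicates differed by more than sampling noise. Ctla4 and Il7r were highest in replicate 3, at 612 and 337 TPM, and Id3, a regulator of T cell differentiation, was lowest there, at 76.0 TPM against 278 and 223 in replicates 1 and 2. The chemokine receptor gene Cxcr6 stood at 225, 184 and 44.0 TPM and Tsc22d3, a gene induced by glucocorticoids, at 186, 220.3 and 671 TPM. These genes varied beyond sampling noise and also under the trended dispersion of edgeR, and Id3, Cxcr6 and Tsc22d3 were named after their values were seen. Immunoglobulin and haemoglobin genes had the widest ranges among varying genes with a mean count of at least 100 that shared no position with another gene, apart from the pseudogene Rps13-ps2. Ighg1, a heavy-chain constant gene on mm10 chromosome 12 from 113325240 to 113330523, had 653, 3 and 1266 counts. This made a 619-fold difference between replicates 3 and 2, with a counting interval of 211 to 3005. Hbb-bs, on chromosome 7 from 103826534 to 103828096, had 1128, 3 and 25.6 counts, a 340-fold difference between replicates 1 and 2 with an interval of 116 to 1649.

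Ighg2c and Ighg2b differed 253-fold and 114-fold, with replicate 3 highest for both. Hba-a2, Hba-a1 and Hbb-bt were at least 270-fold, 144-fold and 114-fold higher in replicate 1 than in replicate 2, which had under 1 count of each, though the split between these copies is uncertain. The other 3 of the 10 genes with the widest ranges were Rps13-ps2, at least 392-fold, and 2 genes whose ranges are uncertain because they share positions with others. Rps13-ps2 is a processed pseudogene that overlaps no other gene, and reads shared with its parent gene were not tested. The 2 genes were a second Zc3h11a entry that overlaps another of that name, at least 532-fold, and Gm45837, which overlaps Arap1, Mir139 and Pde2a, at least 103-fold.

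The chi-square per degree of freedom was 11.4 for replicates 1 and 2 over 14752 genes, 30.7 for replicates 1 and 3 over 14590 genes and 30.3 for replicates 2 and 3 over 14650 genes, against 1.00 to 1.01 for simulated sampling noise. Of 8483 genes with a mean count of at least 100, 37 differed over 2-fold between replicates 1 and 2, 538 between 1 and 3 and 419 between 2 and 3. Spearman's rho was 0.975, 0.941 and 0.946, across genes, which are not independent replicates. Per gene, 8492 of 12997 tested genes (65.3%) varied beyond sampling noise, and 2003 of these also ranged over 2-fold. Replicate 3 lay farthest from the mean of the 3 in 1427 of the 2003, replicate 1 in 374 and replicate 2 in 202. Without replicate 3, 4188 genes varied, and without replicate 1 or 2, 6630 or 6994 did. Under the trended dispersion of edgeR, 149 genes varied, and 675 had an unadjusted p under 0.05. Of the 149, the fixed lists held 5 erythroid markers, 2 genes each of the resting, interferon-stimulated and chemokine receptor lists, and 1 each of the Treg identity, checkpoint, immediate early, B cell and plasma cell lists. The other fixed lists had 0 under edgeR, with an unadjusted p under 0.05 for 5 secreted mediators, 2 effector genes and 1 gene each of the T cell receptor, Th1, fatty acid oxidation and myeloid lists, and for 0 of the rest. Adjusted over the list alone, the dispersion model called 4 secreted mediators, 2 effector genes, 1 Th1 gene and 1 myeloid gene of these.

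The common dispersion of edgeR corresponded to a coefficient of variation of 0.266 between libraries. It was 0.156 without replicate 3, 0.293 without replicate 1 and 0.322 without replicate 2.

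Deviations of whole lists were compared with random lists matched on mean count, on the log2 scale and in replicates 1, 2 and 3. The interferon-stimulated genes had median deviations of 0.59, 0.40 and -0.97, and all 12 were lowest in replicate 3. Erythroid markers deviated by 3.67, -2.58 and -1.07, plasma cell markers by -0.16, -1.17 and 1.33, and B cell markers by 0.32, -0.63 and 0.18. The T cell receptor list, at -0.29 in replicate 3, and the Treg identity list, at -0.26, also lay below the central 95% of matched lists there. So did the secreted mediators at -0.46, checkpoint receptors at -0.34, chemokine receptors and adhesion at -0.32, immediate early genes at -0.22, Th2 at -0.53, Th17 at -0.51 and Tfh at -0.45, the last 3 over at most 4 tested genes each. In replicate 1 the cell cycle list lay below matched lists at -0.18, while the secreted mediators at 0.28, checkpoint receptors at 0.20, Tfh at 0.38, T cell receptor list at 0.13 and Treg identity list at 0.13 lay above. In replicate 2 cell cycle at 0.17, Th1 at 0.25, chemokine receptors and adhesion at 0.22, secreted mediators at 0.20, glycolysis at 0.18, fatty acid oxidation at 0.15 and the T cell receptor list at 0.13 lay above. These signs were the same with DESeq2 size factors and with raw totals.

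**Figure D3:**
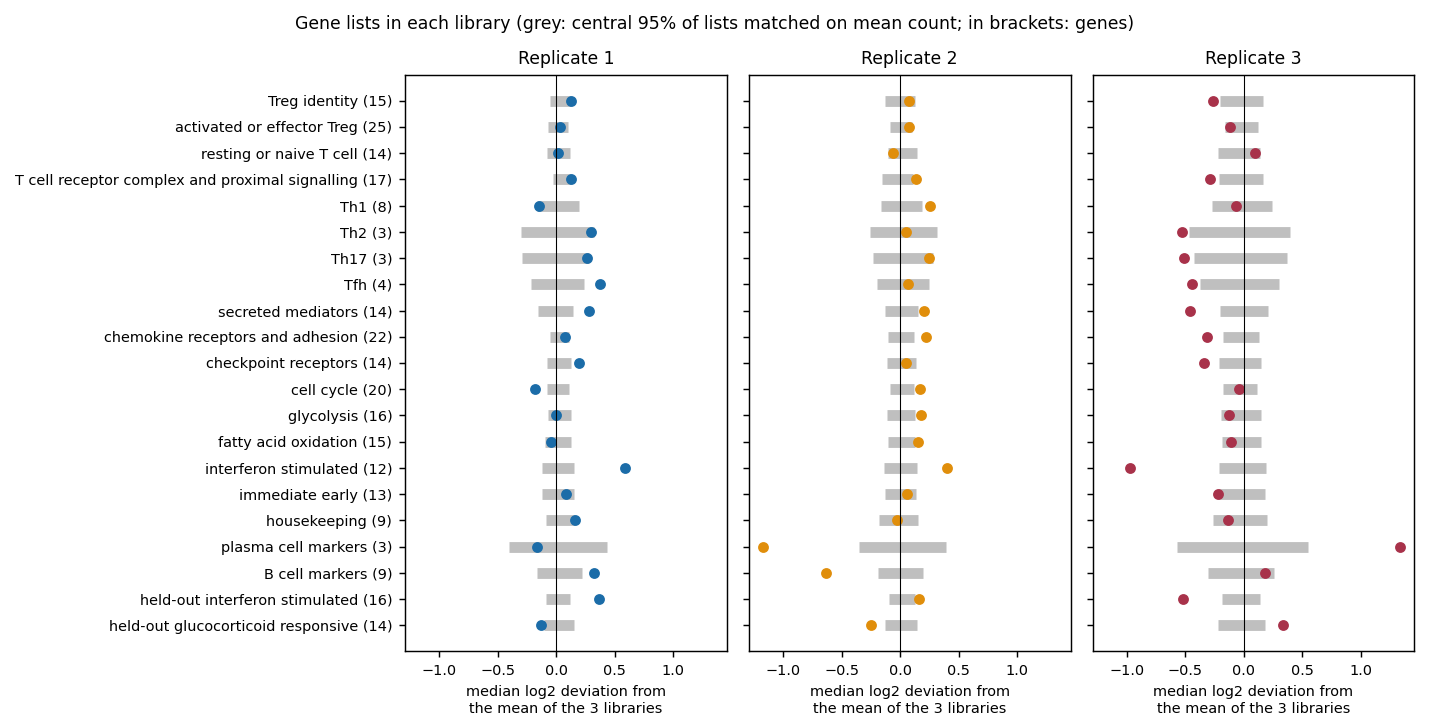
Median log2 deviation of gene lists from the mean of the 3 libraries on the horizontal axis, with a panel per replicate, the number of genes in brackets and the central 95% of matched random lists in grey. The interferon-stimulated list was at 0.59, 0.40 and -0.97, and the plasma cell markers were at -0.16, -1.17 and 1.33.

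T cell receptor V genes were compared to ask whether the libraries shared V gene usage. Counts summed per V gene do not resolve clones, so shared clones cannot be told from them. Separate sorts may also share usage, so the comparison cannot tell a single sort from separate ones. The V genes with the widest ranges were Trav6d-3, with 0, 22 and 11.7 counts and at least 8.12-fold higher in replicate 2 than in replicate 1, and Trav9-4, Trav7-6, Trav8n-2 and Trav8-1, which differed 3.05-fold to 4.14-fold. Their reads are uncertain, since Trav genes are near-identical copies. Over 121 V genes the chi-square per degree of freedom was 2.73, above sampling noise but below the median of 5.22 for matched sets, whose central 95% ran from 3.95 to 7.85. The ratio to the matched median was 0.524, at percentile 0 of the matched sets, which were matched on mean count only. Without replicate 3 the ratio was 0.815, at percentile 11.3 and so within the matched sets, and without replicate 1 or 2 it was 0.405 or 0.475, at percentile 0.

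Transcript shares were examined for 12 genes of regulatory and other T cells. The leading Foxp3 transcript was Foxp3-207, annotated as a target of nonsense-mediated decay, on mm10 chromosome X from 7579669 to 7593105, with 78.8% ± 2.40 of the gene's TPM (SD, n = 3). The protein-coding Foxp3-206 followed with 10.1% ± 3.02. The 4 of 10 Foxp3 transcripts with a 3' UTR of at least 1000 bases together had 1.26% ± 0.69. Foxp3-207 lacks the coding exon from 7592159 to 7592235. The other transcripts with its untranslated exon from 7585812 to 7585894 were all among these 4. Reads across the missing exon were not examined, so the share does not show that most Foxp3 RNA is a decay target. Il2ra-201 had 75.7% ± 1.78, Ctla4-201 98.7% ± 1.26, Tcf7-201 98.7% ± 0.444 and Lrrc32-201 70.4% ± 2.26, each protein-coding. For Helios, Ikzf2-205, a retained-intron transcript, led with 53.7% ± 5.51, and the protein-coding Ikzf2-201 had 33.5% ± 3.65. Ikzf1-204 had 78.9% ± 4.25, Ikzf4-201 65.0% ± 8.87, Ptprc-203 50.8% ± 7.69 and Il1rl1-201 76.0% ± 17.1, and Pdcd1 had 1 annotated transcript. The second transcript quantification gave the same leading transcript in 11 of 12 genes. The exception was Entpd1, which encodes CD39, where Entpd1-204 led with 44.4% ± 1.88 and Entpd1-208 led in the second. Shares are model estimates from short fragments.

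**Figure D4:**
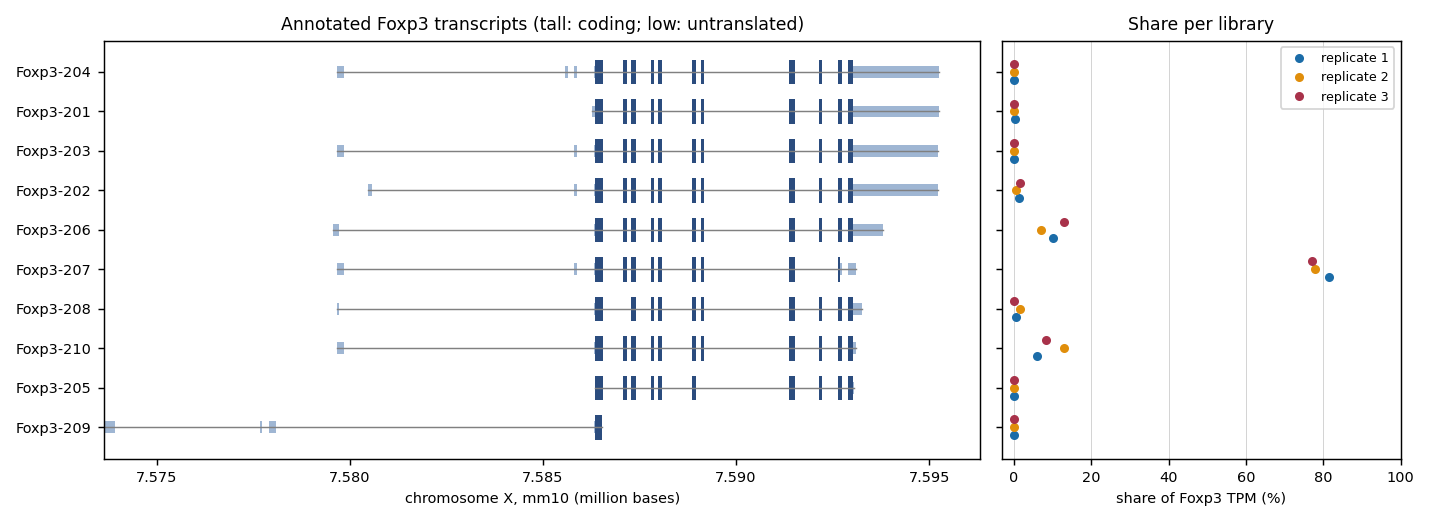
Exons of the 10 annotated Foxp3 transcripts along mm10 chromosome X, tall where coding and low where untranslated, beside the share of Foxp3 TPM in percent with a point per library. By model estimate Foxp3-207 had 78.8% on average, and the 4 transcripts with a 3' UTR of at least 1000 bases had 1.26% together.

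The last question was how far the deposited quantifications gave the same levels. For Foxp3, the M4 count was 2.18, 2.25 and 2.29 times the main fragment count in replicates 1, 2 and 3, against medians of 1.07, 1.09 and 1.11 for 1775 genes with a similar coding share. For Ikzf2 the ratio was 0.201, 0.213 and 0.242, and for Il2ra it was 0.502, 0.548 and 0.526. Across 8118 genes the ratio went with the coding share, with rho of 0.516, 0.540 and 0.545. Across genes the main TPM and the M4 counts per coding base had a Spearman rho of 0.930 ± 0.00465 (SD, n = 3), and the second quantification summed per gene had 0.722 ± 0.0243. Across transcripts the second quantification had 0.675 ± 0.0125. With only features at TPM of at least 1 in both, these were 0.933, 0.955 and 0.866. The second quantification put 17.4% of its TPM on Gm29013-201, an unprocessed pseudogene transcript with 0 counts in the main one, and 4.39% on Mir6236-201, a microRNA. Genes and transcripts are not independent replicates in these correlations.

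**Figure D5:**
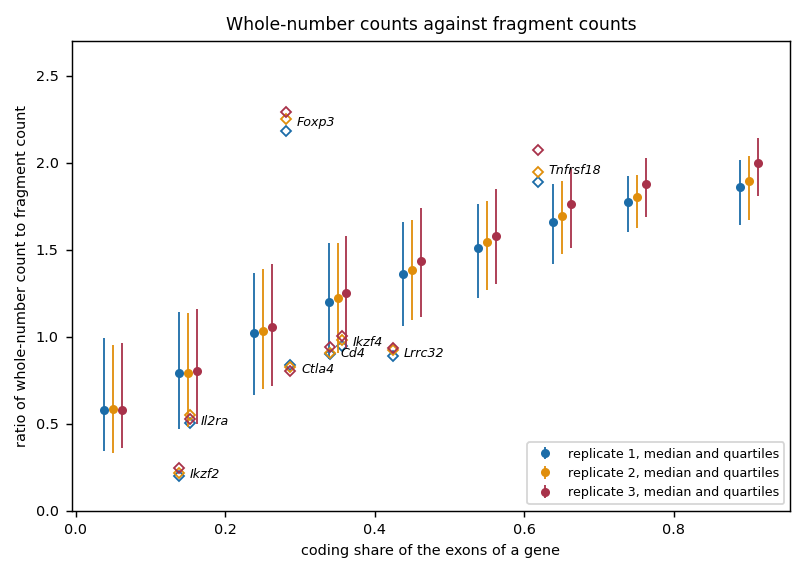
Ratio of M4 count to main fragment count on the vertical axis against the coding share of a gene's exons on the horizontal axis, with dots and bars for the median and quartiles of genes in each bin and open diamonds for named genes, per library. The median was 0.576 in the lowest and 1.86 in the highest bin of replicate 1, and Foxp3 lay at 2.18 there.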

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

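The tests of 1 pool of RNA, of plasma cells, of near-identical gene copies, of the isoform model, of a general loss of 3' UTR fragments, and those of shared reads and of GC content for the glucocorticoid genes were chosen after the result was seen, as was the test of shared reads for the interferon genes.

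PhiX, a bacteriophage genome added to sequencing runs, took 12408, 16132 and 5810 fragments in replicates 1, 2 and 3, or 0.113%, 0.166% and 0.0871% of all fragments. These entries belong to no comparison, and the counts lay above the 3 that a count of 0 allows. The meaning of the 26248 short numeric IDs is not given in the sources used here. Summed over all of these IDs, 13.0, 12.08 and 14.02 fragments were assigned in replicates 1, 2 and 3. The limit of 3 counts is for a single entry, so it does not apply to these sums. The ERCC sequences took 0 fragments.

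Interferon-stimulated genes were lower in replicate 3 and glucocorticoid-responsive genes higher, a pattern first seen in Ifit1 (56.2, 38.2 and 13.0 TPM) and Tsc22d3 (186, 220.3 and 671 TPM); rRNA (3.10% of fragments against 2.23% and 2.05%) and plasma cell markers were also higher there, and the T cell receptor (-0.29), Treg identity (-0.26) and other lists lower. In lists drawn up afterwards from other genes, the 16 held-out interferon genes deviated by -0.52 (log2) in replicate 3, at percentile 0 of matched lists. The 14 tested held-out glucocorticoid genes deviated by 0.33, at percentile 100. There 16 of 16 interferon genes were lowest and 11 of 14 glucocorticoid genes highest, as in the genes first seen. Matched random lists do not allow for genes that vary together, so they cannot exclude chance. The chemokine receptor and adhesion list also lay at percentile 0 there. Under the trended dispersion 0 of the 16 interferon and 3 of the 14 glucocorticoid genes varied. That dispersion was estimated from these same 3 libraries, and its test recovered 0% of genes simulated at 1.5-fold. The low counts therefore do not argue against the pattern. A trend on GC content and transcript length left -0.47 and 0.37, and thinning replicates 1 and 2 to the depth of replicate 3 left -0.53 and 0.33, which argues against either as the whole cause. In the M4 counts the 12-gene interferon list stood at -0.83 in replicate 3, against -0.97 in the main counts. The held-out interferon list stood at -0.54 there, beyond the -0.18 to 0.13 of its matched lists. The held-out glucocorticoid list stood at 0.25, beyond the -0.21 to 0.22 of its matched lists. The assignment of shared reads by the main quantification alone therefore does not account for these deviations. The libraries may differ in cell composition, RNA quality or how the cells were handled or sorted, but no label gives a date or sort, and no biological explanation was tested, because the design has no second group.

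Immunoglobulin and haemoglobin genes as a set differed many-fold between libraries called technical replicates of 1 sample. The median log2 range was 5.47 over the 15 such genes with a mean count of at least 10. Ighm, a member of the set, did not differ many-fold, at 961 ± 159 TPM (SD, n = 3). Nor did the B cell marker Cd79b, at 55.7 ± 4.97 TPM. The many-fold differences therefore leave the levels of Ighm and Cd79b unexplained. Over the 18 tested erythroid, B cell and plasma cell markers, the median range was 2.08 against at most 1.06 in 10000 matched lists. Their lists were fixed before the data were seen, but Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Ighm and Igkc are also among the 15. The test is therefore not independent of the pattern that prompted it. It argues against 3 draws from 1 pool of RNA with none added afterwards but leaves a shared pool of T cell RNA possible. The median range was 4.57 in the M4 counts, over the 13 of the 15 genes in that table. How the M4 counter treats reads shared by near-identical copies is not known, so this range cannot exclude reads moved between them. All 6 erythroid markers, which include the haemoglobin genes, were highest in replicate 1. Reads moved only among the haemoglobin copies would leave some of them lower there. The 3 tested plasma cell markers, none of them an immunoglobulin gene, had a median deviation (log2) of 1.33 in replicate 3, where each was highest. It was -1.17 in replicate 2, where Jchain (43.4, 4.70 and 69.6 TPM) and Mzb1 were lowest but Derl3 (2.10, 3.68 and 5.83 TPM) was not. RNA of plasma cells is a hypothesis that these values allow. Immunoglobulin V genes, 8.54 times higher in replicate 3 than 2, lie on the same transcripts as immunoglobulin constant-region genes and add no evidence. For red blood cells in replicate 1, where Hbb-bs was at 288 TPM, other red cell genes summed to 1.29 times the higher of the other libraries, and their median deviation was 0.94 there with 3 of 5 tested highest, which leaves it open because Bpgm and Slc25a37, which many cells express, make most of the sum; without this pair, left out after the values were seen, the ratio was 7.92. What stays open is whether these are cells or free RNA and at which step they entered, and no biological difference between groups was tested, because the design has 1 group.

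Few Foxp3 fragments were assigned to transcripts with a long 3' UTR, at 4.24%, 1.16% and 3.51% in replicates 1, 2 and 3. The second quantification likewise put at most 5.61% of Foxp3 fragments on transcripts with a 3' UTR of at least 1000 bases in any library. This argues against the isoform model of the main quantification alone as the cause. Both quantifications assign reads to annotated M21 transcripts, so the comparison cannot exclude an effect of the transcript set they share. A general loss of 3' UTR fragments was excluded as the whole cause, since over genes with both kinds of transcript the median share on the long ones was 75.9% or more in each library and both quantifications, although Foxp3, at percentiles 3.63 to 7.42, was not alone in its low share. The high ratio of M4 count to fragment count for Foxp3 bears on this pattern only if the M4 table counts reads over coding sequence, which is inferred. The allele Foxp3CreERT2 named in the labels may also alter the native 3' UTR, which was not tested because no sequence of the allele and no library without it were at hand.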

How the results depend on the processing

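The gene sums of the second transcript quantification, M4 counts for the V genes, the removed shifts and the trended dispersion were tests chosen after the result was seen. Genes detected stayed between 8661 and 13240 against 11943, and effector minus resting between -1.43 and -0.48, negative in each. The chi-square per degree of freedom of the library pairs stayed between 7.31 and 39.1.

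The median level of the Treg identity list was 6.38 with the second quantification, against 7.33, and 7.11 after the shift of all genes was removed. That shift was a median of 0.82, 0.74 and 0.63 (log2, main over second) in replicates 1, 2 and 3, over genes at TPM of at least 1 in both. Genes that vary between libraries numbered 5473 among whole-number genes, where fewer genes were tested, and 149 under the trended dispersion, whose construction raises the variance. Leaving out each library in turn gave 4188 to 6994. The coefficient of variation was 0.159 as the median of DESeq2 gene-wise dispersions, and 0.156 to 0.322 with each library left out. The V gene ratio was 0.405 to 0.815 with each left out, and without replicate 3 it no longer lay below the matched sets. The rank correlations with the second quantification were 0.955 per gene and 0.866 per transcript with only features at TPM of at least 1 in both, which removes the least certain values. For the others the cause was not tested.

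Of 159 gene levels, 98 moved by more than 1 SD with the second quantification (8 up), or 28 (20 up) after its shift was removed, and 91 with TMM-scaled CPM (72 up), which are not divided by length. With M4 counts per coding base 95 of 158 moved (83 up), or 54 (30 up) after a shift of -0.43, -0.38 and -0.43 was removed, and without mitochondrial genes 1 of 159 did. Leaving out a library moved 33 of the 159 levels by over 1.5 times; a mean of 3 cannot move by 1 SD in this way. Of 26 other list medians, with no shift removed, 18 moved with M4 counts (17 up), 18 with the second quantification (2 up), 15 with members below TPM 1 left out (15 up) and 9 with a pseudocount of 0.1 (0 up). Of 12 isoform shares, 8 moved with the second quantification (1 up). Depth limits genes near the floor, at a CPM of 0.273 to 0.450, where neither absence nor a difference can be told.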

Other observations

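The 4 lists named here were drawn up, and their tests chosen, after the data were seen. The 9 glucocorticoid or stress genes seen in the data, among them Per1, Fkbp5 and Tnfaip3, had a median log2(TPM + 1) of 5.21 ± 1.23 (SD, n = 3) at percentile 98.0, and all 9 varied over all genes, 9 adjusted over the list alone and 9 under the trended dispersion. They were picked because they varied, so these counts are not independent evidence. Their median deviations were -0.77, -0.40 and 1.32 in replicates 1, 2 and 3. The 15 held-out glucocorticoid genes, led by Nfkbia at 492 ± 107 TPM and Txnip at 415 ± 285 TPM, were at 5.28 ± 0.33 and percentile 99.6, with 13 of 14 tested varying over all genes, 13 adjusted over the list alone and 3 under the trended dispersion. Their deviations were -0.13, -0.25 and 0.33, with an SD of 0.59 among members in replicate 3.

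The 16 held-out interferon genes, led by Ly6a at 599 ± 168 TPM (SD, n = 3), were at 6.12 ± 0.61 and percentile 100, with 15 varying over all genes and 15 adjusted over the list alone, and 0 under the trended dispersion of edgeR, with 4 at an unadjusted p under 0.05. Their deviations were 0.37, 0.16 and -0.52. Of 10 other red cell genes 9 were measured, Ahsp not being found, at 0.95 ± 0.69 and percentile 20.2, with 5 of 5 tested varying over all genes, 5 adjusted over the list alone and 2 under the trended dispersion. Their median deviations were 0.94, -0.88 and -0.06, above matched lists in replicate 1 and below them in replicate 2. GC content and transcript length together explained 0.902%, 3.19% and 1.29% of the variance of the deviations in replicates 1, 2 and 3.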
